A study of Mus musculus with 6 samples.

How the data were processed

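Total RNA was taken from individual hearts at E10.5 by Trizol extraction, DNase treatment and column cleanup, per the labels' protocols, and genotypes were determined on tissue from outside the heart. Libraries were prepared with TruSeq adaptors from mice of C57BL/6 background, per the labels. The labels place 3 samples in the control group and 3 in the mutant group.

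The submitters' processing notes name FastQC 0.10.1, TopHat2 2.0.8, Bowtie2 2.1.0.0, SAMtools 0.1.19.0, Cufflinks 2.1.1, Cuffdiff and the mm10 genome build. The single file is a Cuffdiff table of 23290 entries that the authors deposited, with 2 genotype columns and 0 columns per sample. FPKM values were computed by the authors per gene and genotype, per the file headers, so replicates are pooled into 1 value. The log2 fold change (mutant over control) and the test statistic are deposited beside each pair of FPKM values, and an infinite fold is written there as a placeholder number. P-values and q-values were deposited by the authors for each tested gene, and the direction of each change was read from the FPKM values since the test statistic has the opposite sign. How Cuffdiff normalised the libraries and estimated dispersion is not given in the sources used here. FPKM carries no read count, so depth per sample is unknown and no counting interval is given. Cuffdiff tested 15387 entries. It marked 7742 as too low for a test (highest FPKM 0.100), 96 as failed and 65 as holding too many fragments, and these were left out of all tests. Another 86 tested entries stood at 0 in 1 genotype. None of them was called, and no fold is given for them.

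The deposited p matched the two-sided normal tail of the test statistic within 1e-05 for all 15301 tested entries with a finite fold, and the deposited q matched a Benjamini-Hochberg adjustment over tested entries. The SE of a log2 fold change was therefore taken as its size divided by that of the test statistic, and 95% intervals assume a normal distribution. No pseudocount was added. Entries carry RefSeq transcript identifiers. A RefSeq gene table of the same mouse assembly named 22999 entries and the GENCODE annotation a further 126, so 99.3% were named, and 245 entries join several gene symbols. Start coordinates were moved from counting at 0 to counting at 1. Genes that overlap or have near-identical copies may share reads in the authors' counting.

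The comparison was control against mutant hearts, with the authors' q under 0.05 as the threshold. Before the data were examined, 23 gene lists, the alternatives and the rule for named genes were fixed. The rule named Casz1 and Nkx2-5, the 10 largest rises and 10 largest falls among called genes with at least 1 FPKM in both genotypes, up to 4 called members of each list or else the 2 members with the highest FPKM, and up to 5 called genes near 0 (under 0.1 FPKM) in 1 genotype. Other genes named in the text are members that passed adjusted over the list alone, or were chosen after their values were seen. Values of some genes that the rule takes are not reported here. For each list the members called over all genes and those called adjusted over the list alone were counted. Among 11906 named genes with at least 1 FPKM in either genotype 45 were called, and calls among the list members of that set were compared with calls among the rest by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 23 lists. The median log2 fold change of each list was placed among 10000 random lists of equal size matched in 10 bins of mean FPKM. Both that percentile and the Fisher's exact test treat genes as independent units. They describe these pooled values and are not tests over hearts. A further 3 lists were added after the called genes had been seen.

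Alternatives covered the q threshold, filters on low FPKM, a minimum fold, pseudocounts of 0.1 and 1 FPKM, centring of fold changes and recomputed adjustments. The list step was tested on simulated data with 14994 genes in 20 runs. A planted log2 shift of 0.5 was found in 20 of 20 runs, and 8 of 120 unshifted lists (6.67%) lay outside the central 95%. Errors were drawn independently for each gene, so the runs do not show how often lists of genes that vary together leave that band. For single genes at a log2 of 2, 77.3% were called, and 3.97% of calls fell on unchanged genes. These shares hold for errors of the size of the implied SE, and the real test statistics spread less (robust SD 0.360). Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures drawn in matplotlib 3.10.9.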

Results

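RNA was sequenced from mouse embryonic hearts at E10.5, when the heart has looped and the chambers are forming. Of the 6 samples, 3 were control hearts and 3 were mutant hearts, each harvested from a separate embryo and described in the labels as biological replicates. Mutant embryos carried floxed alleles of Casz1, a zinc finger transcription factor, on both chromosomes, together with Cre recombinase at 1 Nkx2-5 allele. Control embryos carried 1 floxed Casz1 allele and no Cre. The design asks which genes differ in expression in the heart when Casz1 is mutated. Expression was given per gene as FPKM, the number of fragments scaled by transcript length and by the mapped fragments of the library. The table holds 1 FPKM value per genotype and no value per heart, so the sequencing depth of each sample and the spread between hearts are unknown here. FPKM values summed to 526072 in control and 536805 in mutant hearts. Every FPKM, fold change, p and q below comes from the authors' deposited table unless another test is named, and the standard error (SE) of a log2 fold change is the one implied by its test statistic. The authors' test rests on 3 hearts per genotype.

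Casz1, the targeted gene, was lower in the mutant hearts by a margin that did not pass the authors' test. In the authors' deposited table it stood at 6.61 FPKM in control and 4.68 FPKM in mutant hearts, a 1.41-fold lower level (log2 fold change -0.50, SE 0.306, 95% interval -1.10 to 0.10, q = 1.00). The gene spans chromosome 4 from 148804392 to 148954892 in mm10. The labels do not state which exons were floxed, and the FPKM covers the whole gene model, so transcripts that lack the deleted part still count. Heart cells without Cre keep Casz1 and count as well. Nkx2-5, the homeodomain factor whose locus carries Cre in the mutants only, was at 143.0 FPKM in control and 82.9 FPKM in mutant hearts in the authors' deposited table. Its log2 fold change was -0.79 (SE 0.295, 95% interval -1.36 to -0.21), with an unadjusted p of 0.00755 and q = 0.536. Nkx2-5 lies on chromosome 17 from 26838665 to 26841565. The genotypes therefore differ at both loci, and the comparison does not separate them.

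Across the genome, 65 genes changed at q under 0.05 in the authors' deposited table, of which 47 rose and 18 fell in the mutant hearts. The genes that rose included the neuropeptide gene Cck, the neuronal pentraxin Nptx2, the smooth muscle genes Actg2 and Lmod1, and the epithelial junction gene Cldn6. The genes that fell included the cardiac calcium regulator Pln, the sarcomeric actin Acta1, the axon guidance cue Ntn1 and the macrophage lysozyme Lyz2. Low expression was common among the calls. FPKM was under 1 in both genotypes for 19 of them, 32 of the genes that rose had under 1 FPKM in control hearts, and 24 had at least 1 FPKM in both genotypes. The smallest called change was 2.29-fold. Without the members of the embryo sex, foregut, epithelial and pharyngeal lists, a count chosen after the calls were seen, 31 genes rose and 17 fell.

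Among genes with at least 1 FPKM in both genotypes, Nptx2 rose the most in the authors' deposited table, from 2.76 to 22.3 FPKM (log2 3.01, SE 0.334). Nptx2 lies on chromosome 5 from 144545887 to 144557478. Actg2, the enteric smooth muscle actin, rose 5.62-fold and Cldn6, a claudin of embryonic epithelia, rose 4.84-fold. Cck rose from 11.6 to 51.5 FPKM (log2 2.15, SE 0.353, q = 1.89e-06 in the authors' deposited table). Mrvi1, Lmod1, Crabp2, Vsnl1, Shox2 and Col22a1 completed the 10 largest rises, with log2 fold changes from 1.58 to 1.79. Crabp2 binds retinoic acid, Mrvi1 is a target of cGMP kinase in smooth muscle, and Vsnl1 is a neuronal calcium sensor.

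Only 9 genes fell while keeping at least 1 FPKM in both genotypes. Lyz2 fell the most, from 16.9 to 1.91 FPKM (log2 -3.14, SE 0.434, q = 1.11e-09 in the authors' deposited table). Pcsk6, a proprotein convertase that processes TGF-beta family ligands, fell from 8.53 to 2.24 FPKM (log2 -1.93, SE 0.329). Fam189a2 fell from 24.9 to 8.54 FPKM, Igfbpl1 from 31.0 to 11.3 FPKM and Ntn1 from 15.1 to 5.67 FPKM. Pirt and Gsg1l fell from 4.02 to 1.41 FPKM and from 4.15 to 1.59 FPKM. Acta1, on chromosome 8 from 123891758 to 123894775, fell from 334 to 142 FPKM (log2 -1.23, SE 0.317, q = 0.0273 in the authors' deposited table). Pln, on chromosome 10 from 53278081 to 53379851, fell from 129 to 56.2 FPKM (log2 -1.20, SE 0.298, q = 0.0193 in the authors' deposited table).

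**Figure D1:**
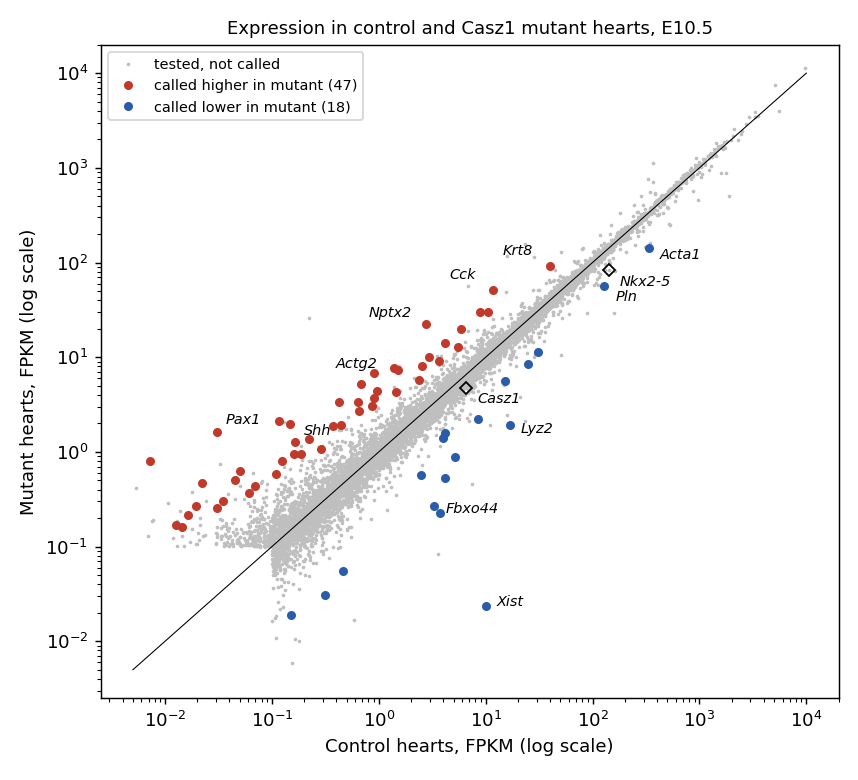
FPKM in control hearts (horizontal, log scale) against FPKM in mutant hearts (vertical, log scale) for the genes tested in the authors' deposited table, 1 point per gene, with the 47 genes called higher in red and the 18 called lower in blue (uncalled genes closest to 0 are left off). Many red points lie under 1 FPKM in control hearts, while Casz1 and Nkx2-5 (open diamonds) lie a little under the line of equal expression.

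**Figure D2:**
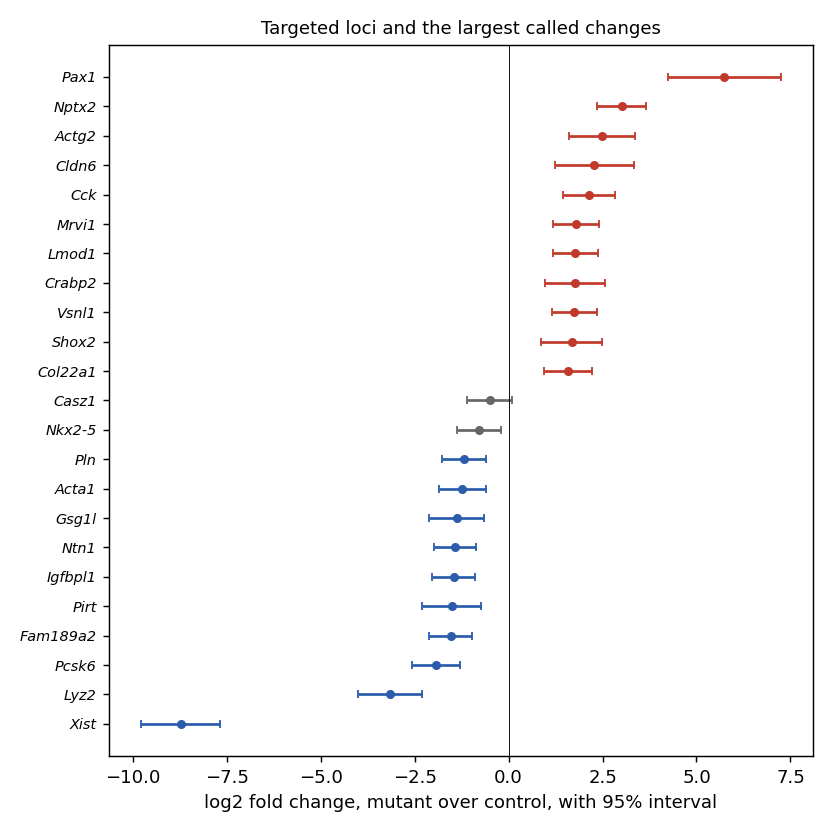
Log2 fold change (mutant over control) of Casz1, Nkx2-5 and the genes with the largest called changes, with 95% intervals from the SE implied by the authors' test statistic. Red and blue mark genes called higher and lower, and grey marks Casz1 and Nkx2-5, which were not called.

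The authors' p-values were shifted towards 1. Of 15387 tested genes, 487 (3.16%) had an unadjusted p under 0.05, against 769 if p were uniform, and 79.8% had a p above 0.5. The median implied SE was 0.317 over the 12150 genes with at least 1 FPKM in either genotype, while their median absolute log2 fold change was 0.0865. The test statistics of these genes were then centred on their median and divided by their robust SD of 0.360, a setting chosen after the data were seen. With this rescaled statistic 471 genes passed higher and 438 lower. Among these same genes the authors' deposited table calls 31 higher and 15 lower, so the higher share of calls was 67.4% there and 51.8% on that scale. The rescaling rests on the spread across genes and not between hearts.

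Several lists of working myocardium had medians below 0 in the mutant hearts. In the list of chamber myocardium and trabecular genes, 0 of 21 tested members rose and 1 fell, Pln, while 4 passed adjusted over the list alone, all lower. Besides Pln these were Irx4, a ventricular homeobox gene (log2 -0.95), the potassium channel subunit Kcne1 (log2 -1.18) and Cited1, a ventricular marker that read 311 and 147 FPKM in the authors' deposited table. Nppa, the atrial natriuretic peptide gene, read 1755 FPKM in control and 888 FPKM in mutant hearts in the authors' deposited table (log2 -0.98, SE 0.392, q = 0.746). Nppa and Nppb, another list member, lie within 5 Mb of Casz1 on chromosome 4. The list median was -0.48, below the medians of all 10000 expression-matched random lists (percentile 0). Enrichment of calls did not pass (two-sided Fisher's exact test, adjusted p = 0.196 over 23 lists). Not all members lay below 0: the atrial light chain Myl7 read 5080 FPKM in control and 7496 FPKM in mutant hearts in the authors' deposited table (log2 0.56) and was not called. In the same pooled comparison Shox2, Epcam and Shh, genes of the sinus node region and of foregut, rose to 8.14, 4.42 and 1.28 FPKM.

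The sarcomere and contraction list also had a median below 0, with few calls. Of 27 tested members 0 rose and 1 fell, Acta1, and 3 passed adjusted over the list alone, with the Z-disc gene Myoz2 (log2 -1.16) and the thin filament gene Lmod2 (log2 -0.81) beside Acta1. Its members had a median of -0.23 (percentile 0, Fisher's exact adjusted p = 0.216). With the rescaled statistic 5 members of the list passed. Myh6, Myh7 and Actc1 were among the 65 entries, at 14 loci, that carried a status for too many fragments and had no usable value. Among skeletal muscle isoforms, 1 of 15 tested members rose, the embryonic myosin Myh3, from 0.0165 to 0.213 FPKM in the authors' deposited table (log2 3.70, or 1.43 and 0.26 with pseudocounts of 0.1 and 1 FPKM), and 0 fell. Adjusted over the list alone, 5 passed: Myh3 and the myogenic factor Myog were higher, Ckm (log2 -1.66) and Tnni2 (log2 -0.98) were lower, and Myf5 was listed at 0 in control hearts. The median of the 10 members with at least 1 FPKM was -0.45 (percentile 0, Fisher's exact adjusted p = 1.00).

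Cardiac ion channel and calcium handling genes were mostly not called in the authors' deposited table. Pln fell, and 26 of 28 tested members did not pass. Adjusted over the list alone 4 passed, of which 3 were lower: Pln, calsequestrin Casq2 (log2 -1.34) and Kcne1. The list median was -0.18 (percentile 0), and calls were enriched (Fisher's exact adjusted p = 0.0246), though 1 called member was lower and 1 was higher. In the list of fatty acid oxidation and mitochondrial genes 0 of 33 members were called and 3 had an unadjusted p under 0.05. Myoglobin Mb (log2 -1.27) and Ckm passed adjusted over the list alone, a count of 2. Atp5b read 1426 and 1334 FPKM and Slc25a4 read 1324 and 1310 FPKM in control and mutant hearts, and the list median was -0.13 (percentile 0).

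Cardiac transcription factors were mostly not called. Shox2, a factor of the sinus node region, rose from 2.55 to 8.14 FPKM (log2 1.68, SE 0.412, q = 0.0161 in the authors' deposited table). Tbx1, a factor of pharyngeal mesoderm and endoderm, rose from 0.647 to 2.69 FPKM (log2 2.05, SE 0.540, q = 0.0366 in the authors' deposited table). None of the 31 tested members fell, 29 did not pass, and 7 had an unadjusted p under 0.05. Adjusted over the list alone 5 passed, with Isl1 (log2 1.04) higher and Irx4 and Nkx2-5 lower. At -0.09, the median was low among random lists (percentile 0.22), and calls were enriched (Fisher's exact adjusted p = 0.0279). That enrichment rests on Shox2 and Tbx1, both higher, and the foregut genes Epcam and Shh rose as well, to 4.42 and 1.28 FPKM.

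The second heart field, outflow tract and pharyngeal mesoderm list had a median above 0. Foxf1, a forkhead factor of splanchnic mesoderm, rose from 0.909 to 3.75 FPKM in the authors' deposited table (log2 2.04, SE 0.491, q = 0.0113), and Tbx1 rose as above. With a pseudocount of 1 FPKM their log2 fold changes were 1.32 and 1.16. The other 21 of 23 tested members did not pass, and 8 passed adjusted over the list alone, all higher, among them Eya1 (log2 1.54), Osr1 (log2 1.08) and Msc (log2 4.21). The list median was 0.31 (percentile 100), with enrichment of calls (Fisher's exact adjusted p = 0.0215) that counts Tbx1 again. Over the 11 members with at least 5 FPKM in either genotype the median was -0.02, so the shift lay in members of lower expression. Foregut and epithelial genes rose in the same pooled comparison, with Epcam at 4.42 FPKM in the mutants. Of the neural crest and neuronal list 0 of 21 tested members were called and 8 had an unadjusted p under 0.05. Sox2, Isl1 and Tfap2b, all higher, made up the 3 that passed adjusted over the list alone, and each of Sox2 and Isl1 belongs to another list as well. Its median was 0.43 over 12 expressed members (percentile 100). Hand2 read 78.2 and 78.5 FPKM and Crabp1 read 21.3 and 35.5 FPKM in control and mutant hearts.

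Smooth muscle genes rose in part. Actg2 rose from 1.37 to 7.72 FPKM (log2 2.49, SE 0.450) and Lmod1, a leiomodin of smooth muscle filaments, from 4.12 to 14.2 FPKM (log2 1.78, SE 0.303) in the authors' deposited table. The other 13 of 15 tested members were not called, and 5 passed adjusted over the list alone, all higher. Of these, transgelin Tagln read 333 FPKM in control and 767 FPKM in mutant hearts in the authors' deposited table, Myh11 had a log2 fold change of 1.52 and the pericyte gene Rgs5 of 1.12. The list median was 0.21 (percentile 100), and calls were enriched (Fisher's exact adjusted p = 0.0142). The foregut and splanchnic genes Epcam, Shh and Foxf1 rose as well, to 4.42, 1.28 and 3.75 FPKM in the authors' deposited table. With 1 pooled value per genotype, it is unknown whether they rose in the same hearts as the smooth muscle genes. Acta2 had a status for too many fragments and gave no usable value.

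In the fixed list of liver and foregut endoderm genes, 5 of 22 tested members rose and 0 fell. Shh, the hedgehog ligand of foregut endoderm, rose from 0.166 to 1.28 FPKM in the authors' deposited table (log2 2.95, SE 0.637, q = 0.00175). Cldn6, Epcam, the adherens junction gene Cdh1 and the forkhead factor Foxa1 rose as well, with log2 fold changes from 2.12 to 2.34. Sox2, Foxa2 and Nkx2-1, the lung and thyroid factor, joined them among the 8 that passed adjusted over the list alone, all higher. The hepatic members Apoa1, Ttr and Afp had log2 fold changes of -0.86, -0.66 and -0.36 and were not called. Calls were enriched (Fisher's exact adjusted p = 7.21e-06), the strongest enrichment of the 23 lists. The list median was -0.01 (percentile 64.3), since its members went both ways. Pax1, a paired box factor of the pharyngeal pouches, rose from 0.0306 to 1.64 FPKM (log2 5.74, SE 0.761, q = 1.76e-10 in the authors' deposited table). These levels are low, and with a pseudocount of 1 FPKM the log2 fold changes were 1.36 for Pax1, 0.97 for Shh and 1.01 for Cdh1, and with 0.1 FPKM that of Pax1 was 3.73.

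In the macrophage and platelet list 1 of 19 tested members fell, Lyz2, 0 rose and 18 did not pass. Adjusted over the list alone 3 passed, all lower, with the platelet chemokines Pf4, at 60.5 and 28.8 FPKM in the authors' deposited table, and Ppbp (log2 -1.51). None of the 14 members with at least 1 FPKM lay above 0, and the median was -0.53 (percentile 0, Fisher's exact adjusted p = 0.170). Erythroid genes gave 0 calls among 16 tested members, 0 with an unadjusted p under 0.05 and a median of -0.03 (percentile 18.6). Hbb-b2 read 460 and 330 FPKM and Alas2 read 126 and 141 FPKM in control and mutant hearts.

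Other cell types of the heart showed small median shifts. Of 29 endothelial and endocardial genes 0 were called in the authors' deposited table and 2 had an unadjusted p under 0.05, with a median of -0.13 (percentile 0.010). Plvap read 85.7 and 74.4 FPKM and Ramp2 read 101 and 92.4 FPKM in control and mutant hearts. Of 33 cushion and extracellular matrix genes 0 were called and 1 passed adjusted over the list alone, Tgfb3 (log2 1.10). Their median was 0.01 (percentile 80.6), and Sparc read 372 and 376 FPKM. Krt8, a keratin of simple epithelia, was the 1 called gene among 21 epicardial list members and rose from 39.7 to 91.5 FPKM (log2 1.21, SE 0.297, q = 0.0169 in the authors' deposited table). The epicardial median was -0.03 (percentile 35.0).

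Cell cycle genes were not called. Of 40 genes of G1/S and DNA replication and 33 of G2/M and mitosis, 0 passed in the authors' deposited table and 0 had an unadjusted p under 0.05. With the rescaled statistic 1 G1/S member and 0 G2/M members passed. Cdk4, the G1 kinase, read 412 FPKM in control and 405 FPKM in mutant hearts, and its cyclin partner Ccnd3 read 254 and 235 FPKM. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, read 228 and 223 FPKM and Cks2 read 134 and 135 FPKM. Both medians were -0.06, at percentiles 0.30 and 0.94 of matched random lists. Of 24 CDK inhibitor and p53 target genes 0 were called, and 1 passed adjusted over the list alone, Perp (log2 -0.93), a desmosomal p53 target. Cdkn1c read 995 and 899 FPKM, Bax read 85.9 and 88.3 FPKM, and the list median was -0.11 (percentile 0.10). In simulated data with the implied errors, 1.42% of genes shifted by a log2 of 0.5 and 21.7% of those shifted by 1 were called. The real test statistics spread less than those errors (robust SD 0.360), so these shares may not hold here. The smallest called change among all genes was 2.29-fold, so small changes of single genes were below detection.

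Signalling, stress and housekeeping lists held no calls over all genes in the authors' deposited table. Of 38 genes of Notch, BMP, Wnt and FGF signalling 4 had an unadjusted p under 0.05, and Fgf9 (log2 -1.46) was the 1 that passed adjusted over the list alone. Their median was 0.09 (percentile 100), and the BMP targets Id3 and Id2 read 179 and 140 FPKM in control and 204 and 157 FPKM in mutant hearts. The hypoxia and glycolysis list (33 genes, 1 with an unadjusted p under 0.05) had a median of 0.05 (percentile 97.8), with Gapdh at 1561 and 1655 FPKM and Ldha at 1079 and 1128 FPKM. Immediate early and stress genes (24 tested, 1 with an unadjusted p under 0.05) had a median of 0.04 (percentile 96.3). Hspa5 read 562 and 537 FPKM and Hspb1 read 494 and 389 FPKM. All 39 cytosolic ribosomal protein genes lay above 0, with a median of 0.11 (percentile 100), 0 calls and 0 with an unadjusted p under 0.05. Rplp1 read 3345 and 3414 FPKM and Rps2 read 1641 and 1754 FPKM.

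Among genes that mark embryo sex, Xist was called. Xist, the RNA that coats the inactive X chromosome of female cells, fell from 10.1 to 0.0238 FPKM in the authors' deposited table (log2 -8.72, SE 0.536). The mutant level is near 0, and the log2 fold change was -6.36 with a pseudocount of 0.1 FPKM and -3.43 with 1 FPKM. Xist lies on chromosome X from 103431517 to 103484957. The other 8 of 9 tested members of the embryo sex list were not called, and 1 passed adjusted over the list alone, Xist. The Y-linked Ddx3y and Eif2s3y had log2 fold changes of 0.64 and 0.55, and the list median was -0.06 (percentile 22.4). The labels do not give the sex of the embryos.

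**Figure D3:**
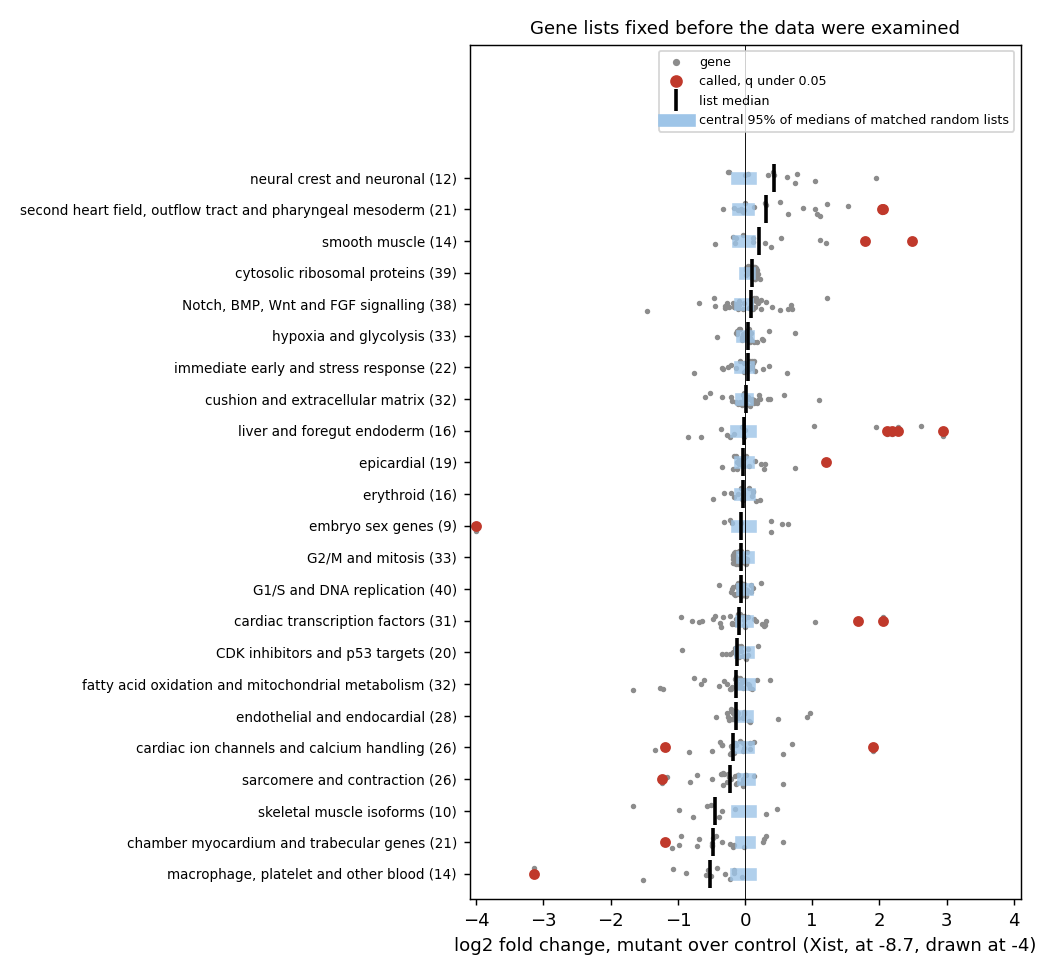
Log2 fold change (mutant over control, horizontal) of the members of the 23 fixed gene lists with at least 1 FPKM in either genotype, 1 grey point per gene, with called genes in red, the list median as a black bar and the central 95% of medians of 10000 matched random lists in blue. The macrophage, chamber, skeletal and sarcomere medians (-0.53 to -0.23) lie left of that band, and the smooth muscle, second heart field and neural crest medians (0.21 to 0.43) lie right of it. Most of the 23 lists lie outside it, also with smaller medians, among them the endothelial, G1/S and ribosomal lists. Only the cushion, epicardial, erythroid, foregut, immediate early and sex gene medians lie inside, so leaving the band does not single out a list.

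Near Casz1 on chromosome 4, Fbxo44, an F-box gene from 148152800 to 148160064, fell from 3.31 to 0.270 FPKM (log2 -3.62, SE 0.553, q = 1.18e-07 in the authors' deposited table). It was singled out for its position after its value was seen, and lies 644 kb from Casz1. Of 84 tested genes within 5 Mb of Casz1, 3 had an unadjusted p under 0.05, against 2.66 for the share elsewhere. The other 2 were Nppa and the angiotensin receptor associated gene Agtrap, at 7.36 and 4.39 FPKM in control and mutant hearts in the authors' deposited table.

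**Figure D4:**
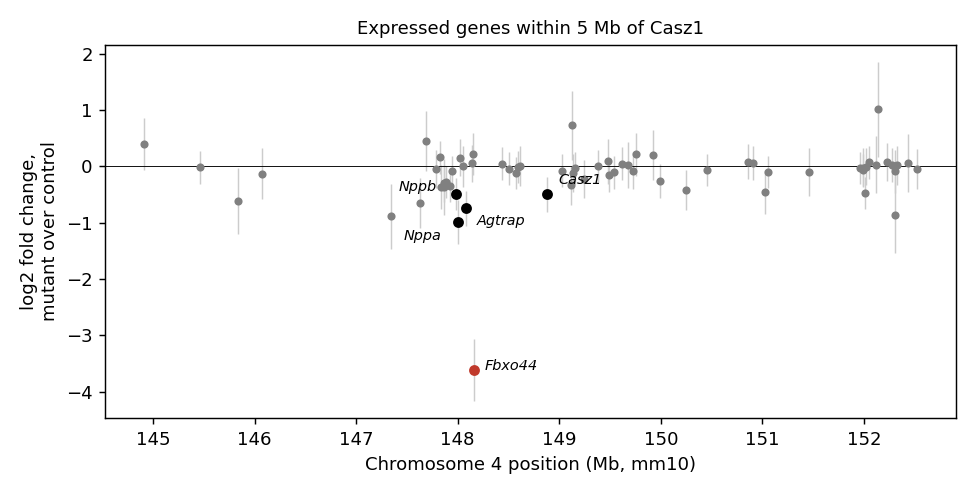
Log2 fold change (mutant over control, vertical) with 1 implied SE against position on chromosome 4 (Mb, mm10) for 67 expressed genes within 5 Mb of Casz1; 1 gene with an SE above 2 is not drawn. Fbxo44, in red, is the called gene at a log2 of -3.62, and Casz1 lies at -0.50.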

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

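The count without sex, foregut, epithelial and pharyngeal genes, the rescaled test statistic and the 3 added lists were chosen after the data were seen. No paired analysis was possible because the table holds 1 pooled value per genotype and no column carries a replicate number, and leaving out single hearts was not run for the same reason. The 65 calls (47 higher, 18 lower) could not be altered by a minimum log2 fold of 1, as the smallest was 1.20 in size, or by centring, which moved all fold changes by 0.017. They numbered 84 at q under 0.10 (58 higher, 26 lower), 48 with at least 0.1 FPKM in both genotypes and 63 without small RNA, unnamed and merged entries. Higher calls numbered 28 of 41 at q under 0.01, 31 of 46 with at least 1 FPKM in either genotype (with the authors' q or a recomputed adjustment), and 31 of 48 without the sex, foregut, epithelial and pharyngeal genes. The first is stricter and the others admit fewer genes by construction. The test statistic was also centred on its median and divided by its robust SD, among genes with at least 1 FPKM in either genotype. It then gave 909 calls, 471 higher and 438 lower, against 46 on the same genes. On that scale the adjusted p-values of Casz1, Nkx2-5 and Nppa were 0.000337, 2.73e-11 and 6.36e-10. These measure the spread between genes and not between hearts. They assume that most genes did not change and that every SE is too wide by the same factor.

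Adjusted over the list alone, calls rose because fewer genes were tested: to 8 in the second heart field and the foregut lists, 5 in the skeletal, transcription factor and smooth muscle lists, 4 in the chamber and ion channel lists, 3 in the sarcomere, neural crest and macrophage lists, 2 in the mitochondrial list and 1 in the CDK inhibitor, cushion and signalling lists. At q under 0.10 the cushion list also had 1. The added epithelial and pharyngeal lists had 16 and 21.

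Most list medians kept their direction and side of the random band: 18 of 23 with at least 5 FPKM, 22 of 23 without a filter and when centred, and 23 of 23 with a pseudocount of 1 FPKM. Centring moves lists and random lists alike, so only the sign of a median could change there. With at least 5 FPKM the epicardial median was 0.0198 and the second heart field median -0.0221, both of the opposite sign, the foregut median was -0.23, the sex gene median -0.20 and the hypoxia median 0.0517. The foregut median turned to 0.0472 without a filter and to 0.00400 when centred. The cause was not tested. Of 55 named genes, a pseudocount of 0.1 FPKM moved 3 (Xist, Pax1 and Myh3) and one of 1 FPKM moved 17 by more than 1 SE. Centring moved 0 and could move none, since its shift of 0.017 is under the SE of each. What depth limits was not measured, since FPKM carries no read counts. The pharyngeal list gave no median at 5 FPKM, with too few members left.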

Other observations

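The 3 gene lists named here, and the tests of noise near the detection floor and of the chromosome 4 segment, were chosen after the called genes had been seen. In an added list of sinus node and sinus venosus genes, 4 of 21 tested members rose, among them Shox2, Vsnl1 and Smoc2, the last from 3.66 to 9.19 FPKM in the authors' deposited table. Adjusted over the list alone 5 passed, with Isl1. The main sinus node pacemaker channel gene Hcn4 read 7.80 FPKM in control and 12.6 FPKM in mutant hearts in the authors' deposited table (log2 0.70) and was not called. The median over 18 expressed members was 0.40 (percentile 100 of matched random lists), and 11 lay above 0. Since the called genes prompted the list, its count is not independent evidence.

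Several called genes belonged to none of the fixed lists. Arg1, an arginase, rose from 0.116 to 2.11 FPKM, the integrin gene Itga7 from 0.684 to 5.21 FPKM, Tdgf1, a co-receptor for Nodal, from 0.907 to 6.76 FPKM and the Wnt receptor Fzd7 from 5.54 to 12.9 FPKM in the authors' deposited table. Sox3, a neural progenitor factor, fell from 4.13 to 0.528 FPKM, Slitrk5 from 5.16 to 0.873 FPKM and Scube2, which helps release hedgehog ligands, from 2.47 to 0.563 FPKM in the authors' deposited table. In an added list of pharyngeal and foregut regional genes 8 of 28 tested members rose and 0 fell, and all 15 expressed members lay above 0 with a median of 1.95, or 0.86 with a pseudocount of 1 FPKM. Pax9, Six2 and Hoxa2, which pattern the pharyngeal arches, were among the 8, at 0.628, 0.960 and 1.85 FPKM in mutant and 0.0497, 0.161 and 0.370 FPKM in control hearts in the authors' deposited table, and 21 members passed adjusted over the list alone. This list too was prompted by the called genes and is not independent evidence. Some members, such as Hoxa2, count as expressed only through their mutant level, which favours rises.

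Xist fell from 10.1 to 0.0238 FPKM in mutant hearts. The Y-linked genes argue against loss of Xist RNA with equal embryo sexes, since the 4 measured had log2 fold changes from 0.38 to 0.64 (median 0.473, SD across genes 0.124). These genes follow the same embryos, so that SD is not the error of the shift. Of the 9 tested sex list members, Xist included, 2 had an unadjusted p under 0.05 in the authors' deposited table. A larger share of male embryos among the mutants may account for Xist, as the same Y-linked median of 0.473 lies near the 0.585 that 2 of 3 control and 3 of 3 mutant males would give. The 4 X-linked list genes other than Xist lay below 0, with a median of -0.22. An effect of genotype on other genes stays open, and any effect of embryo sex on them is confounded with it.

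For the epithelial and endodermal genes that rose in mutant hearts, noise arising separately in each gene near the detection floor is argued against by the foregut list. In that list, fixed before the data were examined, 5 of 19 genes between 0.1 and 10 FPKM were called against 43 of 8700 others (two-sided Fisher's exact p = 4.48e-08). These are the calls already counted for that list, and the test does not cover variation that the genes share. A lower share of myocardium would raise every other cell type alike, yet 4 of 5 such lists had medians below 0. The endothelial and macrophage medians lay below the 2.5 percentile, while the epicardial and erythroid medians (-0.03 each) lay inside the random band. The smooth muscle, second heart field and neural crest lists, not among those 5, had medians of 0.21, 0.31 and 0.43 (percentile 100). These values speak only against a rise of every cell type alike, and a lower share of myocardium is not excluded. Pharyngeal or foregut tissue dissected with more of the mutant hearts could explain the pattern and stays open: an added list of general epithelial genes had a median of 0.740 (0.30 over its 10 members with at least 5 FPKM, 21 of 25 expressed members above 0, and 8 of 44 tested called, all higher, with 16 adjusted over the list alone, 14 higher and 2 lower). That list holds the called genes that prompted it and is not independent evidence, and its 20 expressed members that were not called had a median of 0.50, with 16 above 0. Effects of Casz1 loss, Cre or the altered Nkx2-5 allele were not tested and stay open.

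Fbxo44 fell 12.3-fold beside Casz1. A chromosome 4 segment inherited with the floxed allele could carry a variant of Fbxo44, and the neighbourhood did not decide it: 3 of 84 genes within 5 Mb had an unadjusted p under 0.05 against 2.66 expected (two-sided Fisher's exact p = 0.7496), too few to exclude a single variant. Reads may instead have been assigned to the adjacent F-box genes: the sum of Fbxo2 and Fbxo6 was higher by 48.8% of the 3.04 FPKM that Fbxo44 lost. Fbxo2 was lower (0.340 and 0.149 FPKM), so this rests on Fbxo6, at 10.04 and 11.7 FPKM (log2 0.22, SE 0.370, q = 1.00 in the authors' deposited table), a difference within its error. Without values per heart neither can be excluded, and regulation by Casz1 was not tested. An inherited segment could equally bear on Nppa and Nppb within the same 5 Mb, which was not tested.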
